A study of Homo sapiens with 10 samples.

How the data were processed

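The series measured polyadenylated RNA in NK-92, an established human cell line grown from a natural killer cell lymphoma. The 10 libraries fall into 5 groups of 2: cells before any treatment (0 h), and cells collected 6 h or 24 h after 500 µM deferoxamine (DFO) or 10 µg/mL PPMX-T003 (called T003 here) was added. Per the labels' protocols, Artemis Medium-1 supplemented with human serum (2%) was the culture medium, RNA was extracted with Qiazol, and libraries were made with the TruSeq Standard mRNA kit. The series' design text names paired-end reads of 101 bp from a NovaSeq 6000. That text mentions the 24 h treatment alone, whereas the labels of single samples give 6 h and 24 h, and the sample labels were followed. No label says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

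The table deposited by the authors holds estimated counts per gene symbol, not normalized, for all 10 libraries. Per the series' design text and the submitters' processing notes, reads were trimmed with fastp 0.21.0, mapped to hg38 with HISAT2 2.2.1 and counted with StringTie 2.1.6 against the RefSeq annotation of hg38. The deposited estimated counts are whole numbers, and no rounding was needed. The value 3 occurs 8712 times in the table, more often than 2 (8036 times) or 4 (4664 times), as from read coverage turned into counts, so intervals based on simple counting would be too narrow. How the counting treated strand is not given in the sources used here. Reads of a gene and of an antisense gene that overlaps it therefore cannot be told apart. The table lists 54628 symbols, of which 51616 matched the RefSeq table of GRCh38.p14 used for coordinates. Symbols without a match took 0.633% of all counts. Transcripts of the mitochondrial chromosome are listed at 0, while 3 nuclear copies of them, MTCO1P12, MTATP6P1 and MTND2P28, took 0.633% to 0.735% of each library, so mitochondrial transcripts could not be used as a sign of RNA quality.

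Library totals ran from 107117892 to 143575614 estimated counts, and 23381 to 24330 genes had at least 1 count. The largest single gene, ACTB, took 0.730% to 0.803% of a library. A count of 3, used as the floor for genes at 0, corresponds to 0.0209 to 0.0280 CPM, the usual unit of counts scaled to library size, which covers counting error only. Between the 2 libraries of a group the SD of the log2 difference was 0.122 to 0.182, so no pair held identical values, and none was treated as a copy. Their mean chi-square per gene was 9.26 to 13.4, but counts made from coverage are expected to exceed counting noise, so this does not show that the libraries came from separate cultures.

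Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test (glmQLFit and glmQLFTest). All 10 libraries entered 1 model with group as its only term, scaling was by TMM, and filterByExpr with its minimum count of 10 left 20125 genes. TMM factors lay between 0.991 and 1.01. The model had 5 residual degrees of freedom per gene and a prior of 5.83. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes with an adjusted p under 0.05 are called changed. Standard errors (SE) are the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD over 2 libraries. The 9 comparisons were each agent against untreated cells at 6 h and 24 h, DFO against T003 at each time, 24 h against 6 h within each agent, and the interaction of agent and time.

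Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. The p-values were adjusted over the 24 of 29 lists that had at least 5 tested members, and camera with an estimated correlation and fry were run beside it. Genes are named by a rule. It takes the 8 largest rises and the 8 largest falls of each comparison of an agent with untreated cells or of the agents at a matched time, among called genes with a mean log2 CPM of at least 2 whose libraries do not overlap between the groups. It adds a panel of 32 genes, the 3 members of each list with the smallest p, and markers of other cell types or of RNA quality at a mean of at least 1 CPM. Not every gene that the rule takes is printed below. Where a comparison called 5 or fewer genes, or a gene outside the rule is singled out, the text says that it was chosen after its values were seen. Groups, tests, lists, the naming rule and the first set of alternatives below were fixed before the data were examined.

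The first set of alternatives covered RLE scaling, no filter, a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a model of the compared groups alone, a fold change of at least 2, and leaving out each library in turn. After the data were seen, 3 more were added. They were removal of the trend of each library against GC content and length of transcripts (loess, span 0.4, fitted on genes with a mean log2 CPM of at least 2), a block with the untreated numbers exchanged, and thinning of every library to the smallest total. An adjusted p that DESeq2 set to NA was left as NA and out of all counts. Of the genes tested, 84.3% had a GC content and length. Because the comparisons with untreated cells share the same 2 untreated libraries, 20 sets of unchanged groups were simulated, each with 1 shared untreated group.

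The steps were tested on simulated data in which 200 of 20125 genes were changed, 50 for each fold. For DFO against untreated cells the edgeR step recovered 58% of genes changed 2-fold at 6 h and 68% at 24 h. For T003 it recovered 70% at 6 h and 52% at 24 h. At 1.15-fold it recovered 14%, 6%, 20% and 14% in the same order, so changes of that size were mostly missed in the simulation. The real comparisons at 24 h called more genes than were changed here, 1349 with DFO and 2524 with T003. Their called genes had a median absolute log2 change of 0.203 and 0.201, so small changes did pass there. The simulated rates may therefore not hold for the real data at 24 h. Of 87, 81, 89 and 95 genes called, 9, 10, 6 and 12 were unchanged ones, each a larger share than the 5% aimed at, so the real calls may also hold more false ones than that. In the simulation of T003 at 24 h, a list of 25 genes shifted by 1.2-fold had a camera p of 6.73e-35, and an unchanged list had 0.825. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

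The untreated libraries were taken at 0 h, and no untreated library at 6 h or 24 h was analysed here. In every comparison with untreated cells and between times, the agent cannot be told apart from time in culture. Comparisons of DFO with T003 at a matched time do not have this limit. Results on 1 gene, which the interaction test called, are not reported here.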

Results

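Gene expression was measured in 10 libraries of NK-92, a human natural killer lymphoma line, with 2 libraries per group. Untreated cells were compared with cells given deferoxamine (DFO), a small molecule that chelates iron, or PPMX-T003 (T003), an antibody against transferrin receptor 1, through which cells take up iron bound to transferrin. The comparisons ask how transcript levels changed after 6 h and 24 h with each agent, and whether a chelator and an antibody against the receptor differed. Library totals ran from 107117892 to 143575614 estimated counts. In a principal component analysis the first component took 39.7% of the variance and separated the 4 libraries taken at 24 h, at 6.41 to 11.96, from the 6 others, at -10.36 to -1.77.

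TFRC, the gene of transferrin receptor 1 (chromosome 3, 196049284 to 196082090, hg38, minus strand), rose with both agents at both times. Its level was 171 ± 8.46 CPM (SD, n = 2) in untreated cells, 353 ± 11.5 after 6 h of DFO and 428 ± 12.9 after 6 h of T003. After 24 h it reached 834 ± 0.812 with DFO and 846 ± 1.32 with T003. FTH1, the heavy chain of the iron store ferritin, was at 314 ± 3.82 CPM in untreated cells and fell by 0.20 (log2, SE 0.034, adjusted p = 0.00495) with DFO and by 0.18 (SE 0.034, adjusted p = 0.00631) with T003 at 24 h. Without untreated replicate 2 the FTH1 call ended in both (adjusted p = 0.0621 with DFO and 0.0606 with T003), and it also ended with T003 without replicate 2 of T003 at 24 h (0.0513). FTL, the ferritin light chain, had log2 changes of -0.01 and 0.05 at 24 h (adjusted p = 0.948 and 0.389). SLC25A37, a carrier of iron into mitochondria, rose at 24 h by 0.38 (SE 0.036) with DFO and 0.44 (SE 0.036) with T003. ALAS1, which makes the first intermediate of haem, rose by 0.41 (SE 0.040) and 0.64 (SE 0.040). FBXL5, part of the ligase that degrades iron regulatory protein 2, fell by 0.29 (SE 0.038, adjusted p = 0.000656) with T003 at 24 h. Iron genes went both ways. Of the 21 tested members of the list on iron uptake, storage and sensing, 4 rose and 1 fell with DFO at 24 h (4 and 3 adjusted over the list alone). With T003, 4 rose and 3 fell (5 and 3 adjusted over the list alone). The list was not called by camera (adjusted p = 0.761 and 0.633), whose direction was up for both although the medians (-0.0176 and -0.0215) and means (-0.0951 and -0.000987) were below 0.

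**Figure D1:**
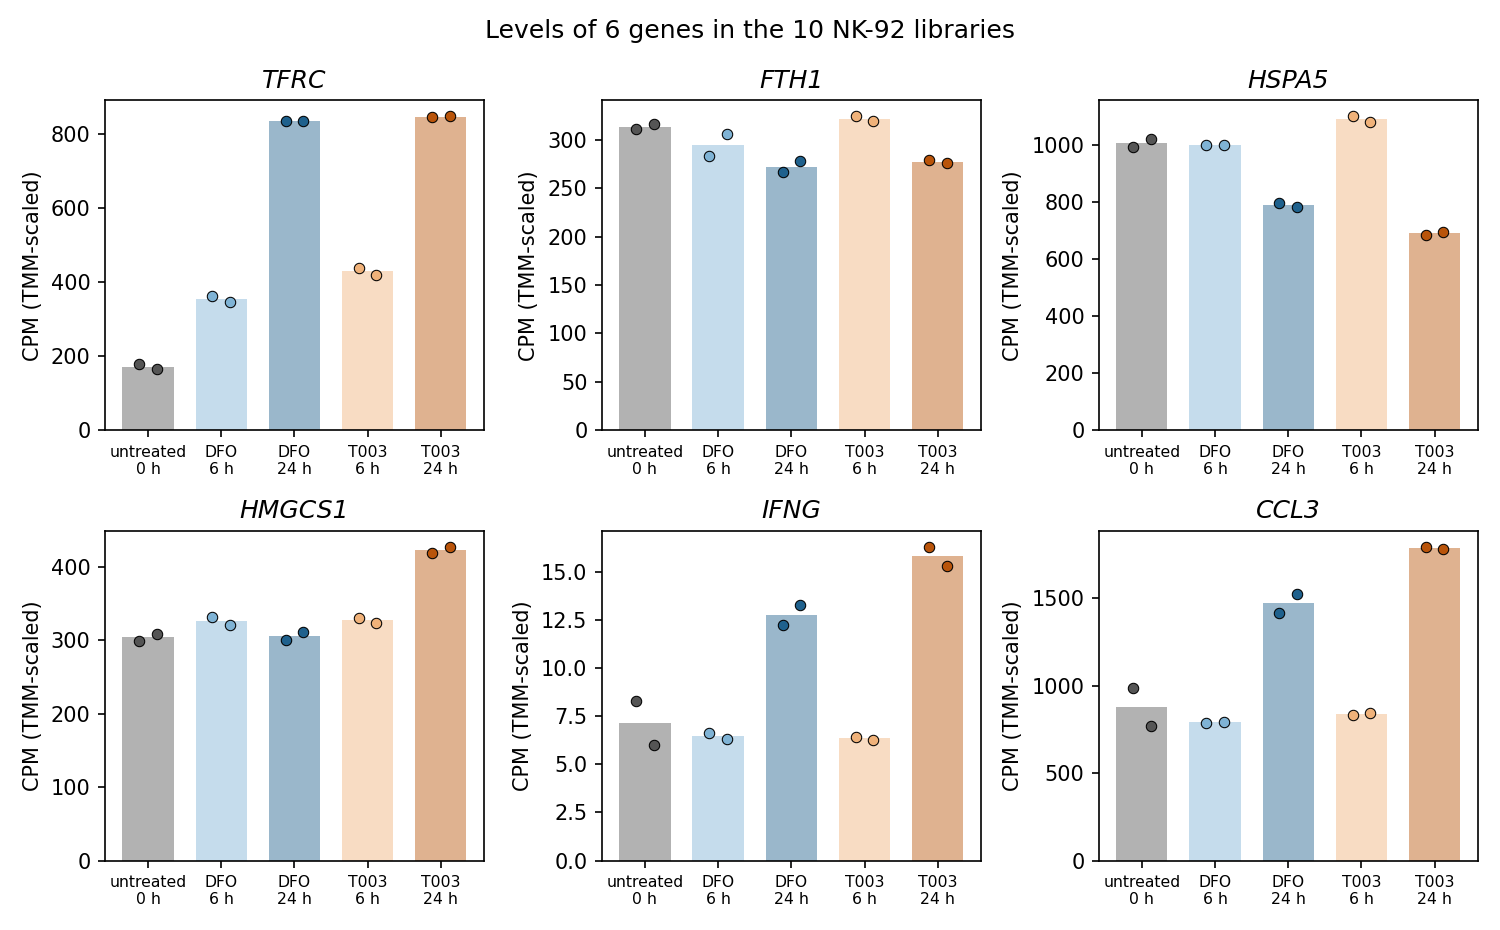
TMM-scaled CPM (y axis, from 0) of TFRC, FTH1, HSPA5, HMGCS1, IFNG and CCL3 in the 5 groups (x axis); bars are means and points the 2 libraries of each group. TFRC stands at 171 CPM in untreated cells and at 834 and 846 after 24 h of DFO and T003, while HMGCS1 is at 306 with DFO and 423 with T003.

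After 6 h of DFO, TFRC rose by 1.05 (log2, SE 0.035, adjusted p = 1.81e-07) and few other genes passed the test. In all, 5 of 20125 genes were called, 3 higher and 2 lower, against 2494 at an unadjusted p under 0.05. With the replicate number as a block the count was 2. The 4 genes called beside TFRC without the block are named because the count is small, after their values were seen. PIM2, a kinase induced by cytokines, fell from 141 ± 4.19 to 118 ± 2.29 CPM (log2 -0.26, SE 0.028, adjusted p = 0.0142), and PYURF, which overlaps PIGY and may share reads with it, fell by 0.60 (SE 0.074, adjusted p = 0.0288). LOC119746555, a long noncoding RNA, rose from 46 and 36 counts in the untreated libraries to 114 and 175. LOC107986708 had 0 counts in both untreated libraries and 40 and 58 with DFO, at least 18.4-fold higher over a floor of 3 counts per library. None of the 24 lists was called by camera. Adjusted over the list alone, 7 of 32 NK receptors, adaptors and transcription factors were higher and 2 lower, and 7 of 23 glycolysis genes were lower, although none of these passed over all genes. The TFRC call held without each library in turn, whereas without DFO 6 h replicate 1 it was the only gene called, and without untreated replicate 2 it was the only called gene shared with the full model, among 9. PIM2 had an adjusted p of 0.14 and 0.0511 without these libraries, and PYURF 0.0631 to 0.366 without either untreated or T003 6 h library or DFO 6 h replicate 1. LOC119746555 had 0.0611 to 0.183 without any untreated or DFO 6 h library, and LOC107986708 0.0611 to 0.222 without any untreated or 6 h library. The count rose to 12 without DFO 6 h replicate 2, and DESeq2 called 522 genes and limma-voom 25.

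After 6 h of T003, TFRC rose by 1.32 (log2, SE 0.035, adjusted p = 1.51e-08). The edgeR test called 6 genes, 5 higher and 1 lower, against 1516 at an unadjusted p under 0.05. PPP1R16B, a regulatory subunit of protein phosphatase 1, rose from 437 ± 3.31 to 496 ± 7.66 CPM (log2 0.18, SE 0.021, adjusted p = 0.0288), and RBM12, an RNA-binding protein gene that overlaps CPNE1, rose by 0.18 (SE 0.024, adjusted p = 0.0333). PIM2 fell by 0.22 (SE 0.028, adjusted p = 0.0333). LOC119746555 rose to 125 and 161 counts, and LOC107986708 to 38 and 55, at least 16.6-fold higher over the same floor. Apart from TFRC these genes were named after their values were seen. The sterol synthesis list was called higher (adjusted p = 0.0227, adjusted p = 0.713 with an estimated correlation), with 0 of 24 members called and 3 adjusted over the list alone. The list of replication-dependent core histones was called lower (adjusted p = 0.0227, adjusted p = 0.434 with an estimated correlation), with 0 of 18 members called. It also holds linker histone genes and the variants H2AX and H2AZ1. Most transcripts of replication-dependent histones lack a poly(A) tail, and the libraries were of polyadenylated RNA, so these values may not show their levels. Without untreated replicate 1 the sterol call ended (adjusted p = 0.41), without untreated replicate 2 the histone call (0.185), and without replicate 1 or 2 of T003 at 6 h both did (0.0662 and 0.166). Both also ended with fry (adjusted p = 0.141) and with no filter (sterol 0.0913, histones 0.0689). The count of genes was 3 and 13 without untreated replicates 1 and 2 and 1 without either library of DFO at 24 h, with TFRC called each time. It was 1 with the replicate number as a block and 81 with DESeq2. The calls other than TFRC ended without most single libraries. The adjusted p was 0.0535 to 0.212 for PIM2 and 0.0535 to 0.132 for PPP1R16B (any library but those of DFO at 6 h) and 0.0655 to 0.383 for RBM12 (any but T003 6 h replicate 2). It was 0.0581 to 0.105 for LOC119746555 (any of the untreated, T003 6 h or DFO 24 h groups) and 0.069 to 0.143 for LOC107986708 (any but those of T003 at 24 h).

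After 24 h of DFO, TFRC rose by 2.29 (log2, SE 0.036, adjusted p = 5.47e-11). IGHM, the immunoglobulin mu constant region, rose by 0.85 (SE 0.040, adjusted p = 3.85e-06). Interferon gamma (IFNG) went from 7.17 ± 1.62 to 12.8 ± 0.717 CPM (log2 0.83, SE 0.125) and the chemokine CCL3 from 875 ± 153 to 1470 ± 78.5 CPM (log2 0.75, SE 0.083). EPHA1, an ephrin receptor, fell from 9.61 ± 1.65 to 0.863 ± 0.235 CPM (log2 -3.47, SE 0.175, adjusted p = 4.75e-06) and MYO5B, a myosin of vesicle transport, from 9.86 ± 2.24 to 1.79 ± 0.246 (log2 -2.46, SE 0.169). The span of EPHA1 overlaps the antisense genes ZYX and EPHA1-AS1, so reads may be shared with them. The transcription factor gene ZNF683, the receptor genes CCR7 and IL9R and IL1RN, the interleukin 1 receptor antagonist, fell by 2.49 (SE 0.196), 1.28 (SE 0.108), 1.19 (SE 0.087) and 1.55 (SE 0.187). HIC1, a transcriptional repressor, rose by 1.01 (SE 0.105). TVP23C-CDRT4, which overlaps TVP23C and CDRT4 and may share reads with them, went from 0.920 ± 0.549 to 15.2 ± 1.17 CPM. With T003 at 24 h it was at 9.87 ± 6.08 CPM. In all, 1349 genes were called, 691 higher and 658 lower. Most changes were small, with a median absolute log2 change of 0.20 among called genes and 67 genes (14 higher, 53 lower) at 2-fold or more.

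With DFO at 24 h 7 lists were called, and 0 of them with an estimated correlation. Genes of ribosome biogenesis and MYC rose, with 17 of 36 members higher and 1 lower (24 and 1 adjusted over the list alone, adjusted p = 3.42e-09, adjusted p = 0.138 with an estimated correlation), among them NOP16 (0.26, SE 0.028) and WDR3 (0.26, SE 0.028). G2/M and mitosis genes were lower in 8 of 34 (13 adjusted over the list alone, adjusted p = 5.03e-06, adjusted p = 0.161 with an estimated correlation), led by the kinetochore genes CENPF (-0.60, SE 0.043) and BUB1 (-0.44, SE 0.036). CDK1 and MKI67 had log2 changes of 0.06 and -0.08 (adjusted p = 0.45 and 0.281). Chaperones of the endoplasmic reticulum and genes of the unfolded protein response were lower in 9 of 20 and higher in 1 (9 and 1 adjusted over the list alone, adjusted p = 4.68e-05, adjusted p = 0.103 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell by 0.35 (SE 0.022) and CALR by 0.22 (SE 0.024). The ATF4 list was lower in 8 of 29 (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.00175, adjusted p = 0.255 with an estimated correlation), with CEBPB at -0.80 (SE 0.074). DDIT3 was at -0.55 (SE 0.086) and SLC7A11, the cystine importer, at -0.98 (SE 0.054). SLC7A11 is also in the list of NRF2 targets and ferroptosis. That list was lower in 7 of 19 and higher in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00175, adjusted p = 0.24 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, fell by 0.59 (SE 0.055).

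Immune genes changed with DFO at 24 h in both directions. NK cytokines and chemokines were higher in 6 of 15 (8 higher and 3 lower adjusted over the list alone, adjusted p = 0.0233, adjusted p = 0.296 with an estimated correlation), with XCL1 at 0.50 (SE 0.069) and XCL2 at 0.44 (SE 0.056). Of the list of NK receptors, adaptors and transcription factors 5 of 32 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.636). The transcription factor gene ID2 rose by 0.41 (SE 0.036) and KLRD1, the CD94 receptor chain, fell by 0.32 (SE 0.037). Of 20 cytotoxic effectors 3 rose and 1 fell (5 and 6 adjusted over the list alone, adjusted p = 0.854), GZMA by 0.17 (SE 0.022). In the IL-2 receptor and STAT5 list 7 of 24 rose and 4 fell (12 and 5 adjusted over the list alone, adjusted p = 0.0789), with DUSP6 at 0.73 (SE 0.083), and CISH and PIM1 at -0.28 (SE 0.027) and -0.31 (SE 0.034). Core histones were called lower with 0 of 18 members passing (0 adjusted over the list alone, adjusted p = 0.0471, adjusted p = 0.255 with an estimated correlation). The limit given above for histones in polyadenylated RNA holds here too. The cytokine list was no longer called without DFO 24 h replicate 2 (adjusted p = 0.116) or without either library of T003 at 24 h (0.0503). The histone call ended without untreated replicate 2 (0.114), DFO 24 h replicate 1 (0.214), T003 6 h replicate 1 (0.0519) or either library of T003 at 24 h (0.0503). The count of 1349 genes fell to 437 without untreated replicate 2, 760 and 527 without DFO 24 h replicates 1 and 2, and 774 when only the 4 compared libraries were used.

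Hypoxia and HIF targets, which iron chelation can raise by blocking the iron-dependent prolyl hydroxylases, were not called with DFO. At 24 h 1 of 33 rose and 5 fell (4 and 5 adjusted over the list alone, adjusted p = 0.278). MXI1 rose by 0.57 (SE 0.078), and BHLHE40 and KDM7A fell by 0.38 (SE 0.028) and 0.59 (SE 0.067). At 6 h the list had 0 called members and an adjusted p of 0.5. PDK1, LDHA and SLC2A1 had log2 changes of 0.00, 0.00 and -0.02 at 24 h, NDRG1 -0.13 (SE 0.117), and CA9, EGLN3 and CDKN1A were too low to be tested. Other lists were not called with DFO at 24 h either. Sterol synthesis had 4 of 24 higher and 0 lower (5 and 0 adjusted over the list alone, adjusted p = 0.149). Glycolysis had 3 of 23 higher and 3 lower (5 and 4 adjusted over the list alone; 0.761), and haem and iron-sulfur cluster genes 2 of 34 higher and 0 lower (3 and 1 adjusted over the list alone; 0.761). Members higher and lower were 0 and 2 of 48 for DNA replication (0 and 1 adjusted over the list alone; 0.603), and 1 and 1 of 25 for p53 targets (1 and 4; 0.563). They were 2 and 5 of 33 for 2-oxoglutarate dioxygenases (3 and 6; 0.424), and 1 and 3 of 29 for interferon-stimulated genes (2 and 4; 0.894). For autophagy they were 0 and 3 of 23 (0 and 3; 0.239) and for the BCL2 family 1 and 4 of 23 (4 and 4; 0.881). No member of the respiratory chain (32 tested; 0.761) or of the TCA cycle (19 tested; 0.603) changed, over all genes or adjusted over the list alone. Median and mean differed in sign for the NK receptor, respiratory chain, interferon and T cell lists, for which camera gave the direction up.

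After 24 h of T003, 2524 genes were called, 1429 higher and 1095 lower, and 119 (28 higher, 91 lower) at 2-fold or more. TFRC rose by 2.31 (log2, SE 0.036, adjusted p = 5e-11), IGHM by 0.93 (SE 0.040), IFNG by 1.14 (SE 0.125) to 15.8 ± 0.704 CPM and CCL3 by 1.03 (SE 0.083) to 1786 ± 10.7 CPM. RGS1, a regulator of G protein signalling, rose from 5.78 ± 0.687 to 11.6 ± 0.223 CPM. CCL3L3, a near copy of CCL3 whose reads cannot be separated from it with certainty, rose from 24.3 ± 9.79 to 60.0 ± 0.210 CPM. EPHA1 fell by 3.78 (SE 0.180), MYO5B by 2.36 (SE 0.168), ZNF683 by 2.40 (SE 0.195) and SLC7A11 by 1.10 (SE 0.054). Among genes of the IL-2 receptor, IL2RA rose by 0.55 (SE 0.072) and IL2RB by 0.34 (SE 0.027), and the cytotoxic effectors GZMB and PRF1 rose by 0.37 (SE 0.034) and 0.29 (SE 0.032). MYC rose by 0.38 (SE 0.042).

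Sterol synthesis genes and SREBP2 targets rose with T003 at 24 h in 19 of 24 members with none lower (22 and 0 adjusted over the list alone, adjusted p = 5.19e-16, adjusted p = 0.0317 with an estimated correlation). HMGCS1, which makes HMG-CoA for cholesterol synthesis, rose from 304 ± 6.74 to 423 ± 6.08 CPM (log2 0.48, SE 0.027, adjusted p = 5.96e-06) and INSIG1 by 0.66 (SE 0.047). The endoplasmic reticulum list was lower in 12 of 20 (13 lower and 1 higher adjusted over the list alone, adjusted p = 2.37e-06, adjusted p = 0.0317 with an estimated correlation), with HSPA5 falling from 1005 ± 20.8 to 689 ± 8.49 CPM (log2 -0.54, SE 0.022). These were the 2 lists of 8 called that held with an estimated correlation. Ribosome biogenesis and MYC genes were higher in 22 of 36 and lower in 1 (23 and 1 adjusted over the list alone, adjusted p = 4.46e-10, adjusted p = 0.0634 with an estimated correlation). G2/M and mitosis genes were lower in 18 of 34 (23 adjusted over the list alone, adjusted p = 2.62e-10, adjusted p = 0.0539 with an estimated correlation), with CENPF at -0.65 (SE 0.043). The ATF4 list had 12 of 29 lower and 3 higher (13 and 3 adjusted over the list alone, adjusted p = 0.00487, adjusted p = 0.213 with an estimated correlation). The NRF2 list had 8 of 19 lower and 2 higher (9 and 2 adjusted over the list alone, adjusted p = 0.01, adjusted p = 0.213 with an estimated correlation). Cytokines and chemokines had 6 of 15 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.0114, adjusted p = 0.231 with an estimated correlation). Core histones were lower in 4 of 18 (6 adjusted over the list alone, adjusted p = 0.0069, adjusted p = 0.17 with an estimated correlation), with H2AC6 at -0.65 (SE 0.089). For this list the same limit of polyadenylated RNA holds. Without T003 24 h replicate 1 the cytokine and histone calls ended (adjusted p = 0.0857 and 0.054). The count of 2524 genes fell to 1164 without untreated replicate 2 and to 1362 and 1420 without replicates 1 and 2 of T003 at 24 h.

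The remaining lists were not called with T003 at 24 h. In the IL-2 receptor and STAT5 list 8 of 24 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.0651). In the DNA replication list 10 of 48 rose and 3 fell (the same adjusted over the list alone; 0.0651). Of the cytotoxic effectors 6 of 20 rose and 6 fell (7 and 7 adjusted over the list alone; 0.653). Members higher and lower were 8 and 4 of 32 for NK receptors and transcription factors (9 and 5 adjusted over the list alone, adjusted p = 0.667), with SLAMF7 at 0.31 (SE 0.024). They were 3 and 5 of 33 for HIF targets (3 and 5; 0.667), 5 and 2 of 23 for glycolysis (5 and 2; 0.667) and 3 and 2 of 25 for p53 targets (3 and 3; 0.804). They were 1 and 7 of 34 for haem and iron-sulfur genes (4 and 7 adjusted over the list alone; 0.757), and 2 and 2 of 32 for the respiratory chain (2 and 2; 0.798). For the TCA cycle they were 0 and 3 of 19 (0 and 3; 0.678) and for 2-oxoglutarate dioxygenases 4 and 5 of 33 (5 and 6; 0.667). Last, they were 1 and 4 of 29 for interferon-stimulated genes (1 and 4 adjusted over the list alone; 0.816), 1 and 3 of 23 for autophagy (1 and 3; 0.667) and 6 and 3 of 23 for the BCL2 family (6 and 4; 0.667), in which BCL2 rose by 0.33 (SE 0.024). Median and mean differed in sign for the NK receptor, glycolysis and T cell lists, for which camera gave the direction up.

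Changes at 24 h ran the same way with both agents. Of the genes called, 546 were higher with both and 460 lower with both, and 0 were called in opposite directions, where independent lists would share 49.1 and 35.8. Examples are TFRC, IGHM, IFNG and CCL3 among the higher genes and EPHA1, MYO5B, IL1RN and SLC7A11 among the lower. Of the 1349 genes called with DFO, 94.7% had the same sign in the change with T003 from 6 h to 24 h, which shares no library with that comparison. Across 10215 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.766 (Spearman rho 0.725) against a mean of 0.472 in 20 simulations of unchanged groups with a shared untreated group, and a covariance of 0.0214 against 0.00439, a difference of 0.017. At 6 h the covariance was 0.0062, and its difference from the simulated mean, which was drawn for the 24 h comparisons, 0.00181. The largest simulated covariance was 0.00611. Pearson r at 6 h was 0.49, against a simulated mean of 0.472 and maximum of 0.573, so no clear excess was seen at 6 h. No simulated draw gave more than 1 gene called in the same direction. With no gene changed in the simulation few calls could arise, so this count cannot show how many shared calls the shared controls add. The changes from 6 h to 24 h, which share no library between the agents, had a covariance of 0.0227. The 2 untreated libraries are too few to give each agent 2 of its own, and part of the excess of shared calls over independent lists may come from these shared controls. Without untreated replicate 2 the shared genes numbered 341, and without DFO 24 h replicates 1 and 2 they numbered 600 and 460.

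**Figure D2:**
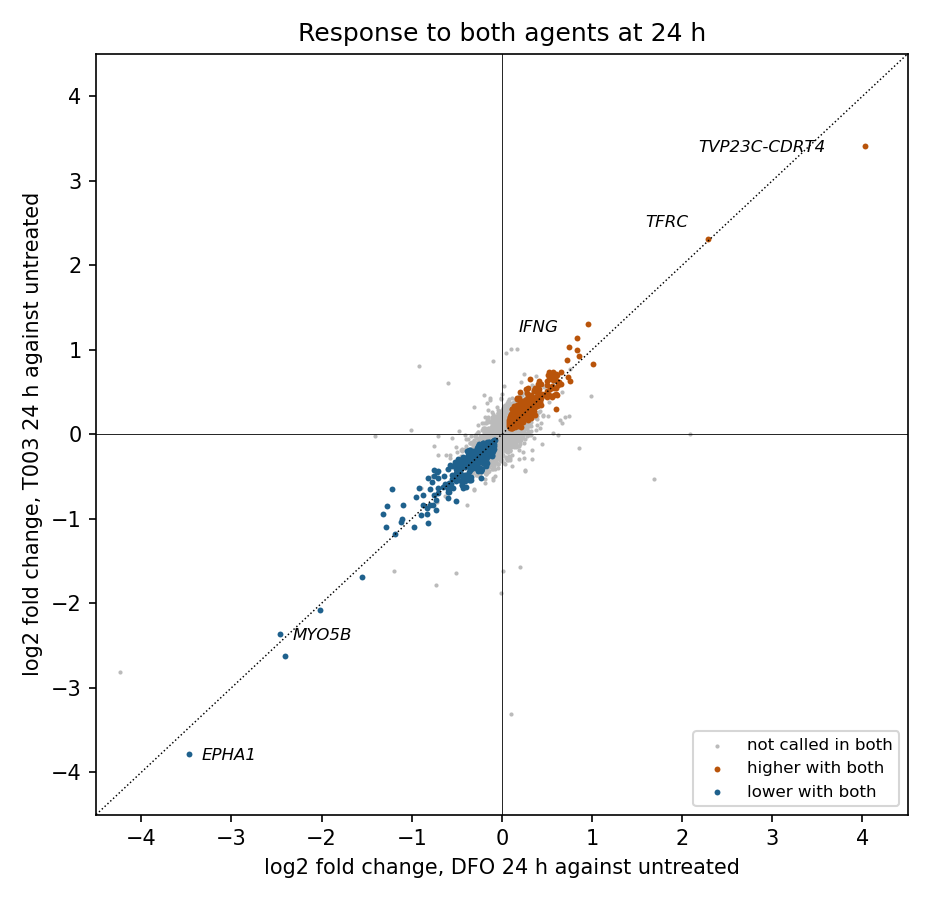
Log2 fold change against untreated cells after 24 h of DFO (x axis) and of T003 (y axis) for genes with a mean of at least 4 CPM; each point is a gene, the dotted line marks equal change, and 2 genes lie outside the axes. The 530 genes higher with both agents and the 417 lower with both (colours) lie close to the line, with TFRC at 2.29 and 2.31 and EPHA1 at -3.47 and -3.78.

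At 6 h DFO and T003 differed in 0 genes with edgeR, against 1334 at an unadjusted p under 0.05, 14 called by DESeq2 and 1 by limma-voom. TFRC was lower with DFO than with T003 by a log2 difference of -0.28 (SE 0.034), which did not pass the test (adjusted p = 0.064). None of the 24 lists was called. The count was 1 or 2 in the other settings that changed it and 1 to 3 in the 6 models without a library of the untreated or 6 h groups.

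At 24 h DFO and T003 differed in 270 genes, 92 higher and 178 lower with DFO, and the sterol synthesis genes were lower with DFO. HMGCS1 was at 306 ± 7.03 CPM with DFO and 423 ± 6.08 with T003 (log2 -0.47, SE 0.027, adjusted p = 6.93e-05). DHCR7, an enzyme of the last step of cholesterol synthesis, differed by -0.35 (SE 0.031, adjusted p = 0.00122). In all, 15 of the 24 members were lower and 0 higher (22 and 0 adjusted over the list alone; camera adjusted p = 3.39e-22), the single list called with an estimated correlation (adjusted p = 0.0253). TFRC did not differ detectably at 24 h (log2 -0.02, SE 0.034, adjusted p = 0.875), and neither did IFNG (-0.31, SE 0.123, adjusted p = 0.287) or CCL3 (-0.28, SE 0.082, adjusted p = 0.138). GZMB was lower with DFO by -0.29 (SE 0.034, adjusted p = 0.00546) and DUSP5, a phosphatase of MAP kinases, by -0.26 (SE 0.026, adjusted p = 0.00231). HSPA5 was higher with DFO by 0.19 (SE 0.022, adjusted p = 0.00539). Of genes outside the lists, CA5BP1-CA5B was lower with DFO (log2 -1.72), at 2.55 ± 1.47 against 8.39 ± 0.626 CPM. AFAP1L2, CBR4, ARHGEF39 and AIG1 were higher with DFO by 0.36, 0.32, 0.31 and 0.30. The AFAP1L2 call ended without either library of T003 at 24 h, and the calls of the others ended without most single libraries.

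Another 5 lists were called between the agents at 24 h with few members passing. DNA replication genes were lower with DFO in 5 of 48 and higher in 1 (19 and 3 adjusted over the list alone, adjusted p = 0.00238, adjusted p = 0.378 with an estimated correlation). G2/M genes were higher in 1 of 34 (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.000134, adjusted p = 0.265 with an estimated correlation). The endoplasmic reticulum list was higher in 1 of 20, HSPA5 (5 adjusted over the list alone, adjusted p = 0.00962, adjusted p = 0.221 with an estimated correlation). Lower with DFO were 2-oxoglutarate dioxygenases (2 of 33 and 3 adjusted over the list alone, adjusted p = 0.0436, adjusted p = 0.364 with an estimated correlation). So were ribosome biogenesis genes (3 of 36 lower, 1 higher; 9 and 4 adjusted over the list alone, adjusted p = 0.0493, adjusted p = 0.407 with an estimated correlation). The ribosome call ended without each of the 10 libraries in turn (adjusted p from 0.0647 to 0.164) and the dioxygenase call without any untreated or DFO library or T003 24 h replicate 1 (0.0616 to 0.164). Both ended with the replicate number as a block (adjusted p = 0.0698) and with no filter (dioxygenases 0.186, ribosome 0.193), and the ribosome call also with fry (0.0596). Without T003 24 h replicate 2 the calls of the endoplasmic reticulum list (adjusted p = 0.109), GZMB (0.0563) and HSPA5 (0.0529) ended, HSPA5 also without replicate 1 (0.0759). The count of 270 genes fell to 20 and 14 without replicates 1 and 2 of T003 at 24 h, 54 and 31 without those of DFO at 24 h, and 97 and 103 without those of T003 at 6 h. It was 49 in the 4 compared libraries alone, 446 with a filter of 1 CPM and 888 with DESeq2. With the replicate number as a block it was 117, and 132 with the untreated numbers exchanged in the block.

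**Figure D3:**
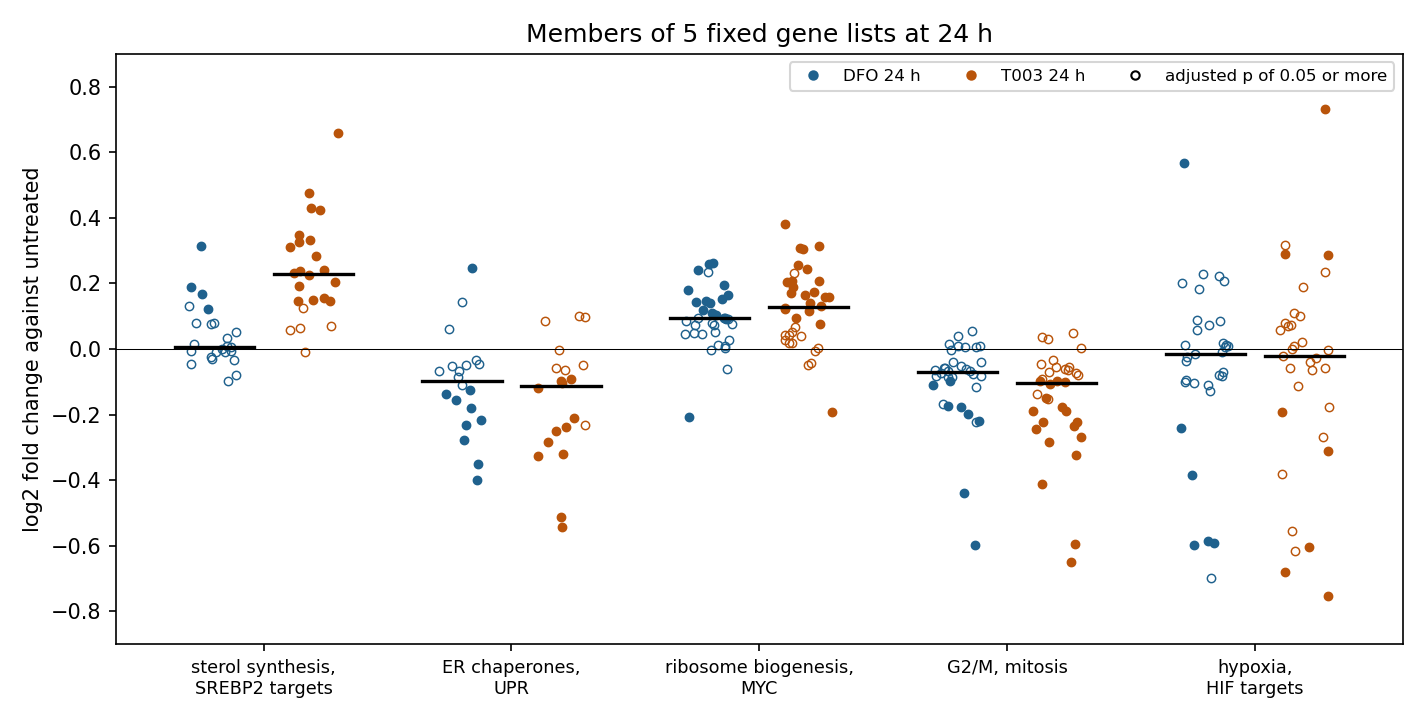
Log2 fold change against untreated cells at 24 h (y axis) of the tested members of 5 lists with DFO and T003 (x axis); each point is a gene, filled where the adjusted p is under 0.05, and black lines are medians. The sterol list has a median of 0.229 with T003 and 0.00754 with DFO, and the HIF list lies around 0 with both.

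Between 6 h and 24 h, 1991 genes changed with DFO (1065 higher, 926 lower) and 2714 with T003 (1520 higher, 1194 lower). Cytokines and chemokines were higher at 24 h in 9 of 15 members and lower in 1 with DFO (9 and 2 adjusted over the list alone, adjusted p = 0.000718, adjusted p = 0.177 with an estimated correlation). With T003 they were so in 6 and 2 (10 and 2 adjusted over the list alone, adjusted p = 0.00221, adjusted p = 0.2 with an estimated correlation). Of the IL-2 receptor and STAT5 list, 9 of 24 were higher and 3 lower with DFO (13 and 3 adjusted over the list alone, adjusted p = 0.00449, adjusted p = 0.137 with an estimated correlation). With T003 these were 10 and 2 (12 and 2 adjusted over the list alone, adjusted p = 0.00991, adjusted p = 0.12 with an estimated correlation). Without DFO 6 h replicate 2 the DFO call ended (adjusted p = 0.0585). Sterol genes were higher at 24 h in 18 of 24 with T003 (21 adjusted over the list alone, adjusted p = 2.34e-12, adjusted p = 0.0472 with an estimated correlation). With DFO 4 of 24 were higher (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.513). Ribosome biogenesis genes were higher at 24 h with DFO (20 of 36, 1 lower; 24 and 1 adjusted over the list alone, adjusted p = 3.2e-09, adjusted p = 0.137 with an estimated correlation). The same list was higher with T003 (21, 1 lower; 24 and 1, adjusted p = 1.17e-08, adjusted p = 0.0867 with an estimated correlation). The endoplasmic reticulum list was lower with DFO (9 of 20, 1 higher; 12 and 1 adjusted over the list alone, adjusted p = 5.15e-05, adjusted p = 0.105 with an estimated correlation). It was also lower with T003 (11, 0 higher; 13 and 1, adjusted p = 1.91e-07, adjusted p = 0.0432 with an estimated correlation). G2/M genes were lower in 14 and 17 of 34 (16 and 23 adjusted over the list alone, adjusted p = 2.15e-05 and 1.17e-08, adjusted p = 0.149 and 0.0807 with an estimated correlation). The ATF4 list was lower in 7 of 29 with DFO (9 lower and 4 higher adjusted over the list alone, adjusted p = 0.0125, adjusted p = 0.285 with an estimated correlation), a call that ended without DFO 24 h replicate 1 (0.0741) or DFO 6 h replicate 2 (0.0668). With T003 it was lower in 9 and higher in 2 (9 and 3 adjusted over the list alone, adjusted p = 0.00991, adjusted p = 0.312 with an estimated correlation). The NRF2 list was lower with T003 in 8 of 19 and higher in 2 (8 and 3 adjusted over the list alone, adjusted p = 0.0307, adjusted p = 0.312 with an estimated correlation). Its call ended without either DFO 24 h library (0.05), T003 24 h replicate 2 (0.0868) or T003 6 h replicate 2 (0.0846), and with the replicate number as a block (0.0535).

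The interaction of agent and time called 4 genes. Among those named after their values were seen, the change from 6 h to 24 h was smaller with DFO than with T003 for HMGCS1 and LPIN1, which rose with T003, and for HSPA5, which fell with both. The LPIN1 call ended without any library but T003 6 h replicate 1 (adjusted p = 0.0533 to 0.228). The interaction count was 7 and 10 without DFO 6 h replicates 1 and 2 and 2 without DFO 24 h replicate 2. The count between times with DFO was 980 without DFO 6 h replicate 1, 1172 and 1035 without DFO 24 h replicates 1 and 2 and 1171 in the compared libraries alone. With T003 it was 1369 and 1599 without replicates 1 and 2 at 6 h and 1474 and 1723 without those at 24 h.

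Markers of other cell types were at low levels or did not change, with exceptions. CD3E (433 CPM), TRBC2 (40.0), TRAC (20.2), TRBC1 (19.7), CD6 (17.3) and CD28 (107) were the T cell markers at 1 CPM or more. The rest of that list, CD3D, CD3G, CD4, CD5, CD8A and CD8B, had means of 0 to 0.0232 CPM. CD28, a costimulatory receptor, rose at 24 h by 0.30 (SE 0.032, adjusted p = 0.000277) with DFO and 0.46 (SE 0.032, adjusted p = 1.24e-05) with T003, while the T cell list was not called (adjusted p = 0.636 and 0.667). JCHAIN (12.9 CPM), CD68 (2.43), ITGAX (3.58) and PECAM1 (1.36) were the B cell, myeloid and vessel markers at 1 CPM or more, and no erythroid or platelet marker reached 1 CPM. ITGAX rose by 0.88 (SE 0.151) with DFO and PECAM1 by 1.49 (SE 0.305) with T003 at 24 h. The ITGAX call ended without untreated replicate 2 (adjusted p = 0.0504) or DFO 24 h replicate 2 (0.0556), and that of PECAM1 without T003 24 h replicate 1 (0.0853) or untreated replicates 1 and 2 (0.0536 and 0.0751). PAX5, a B cell transcription factor gene, fell at 24 h from 0.984 ± 0.575 CPM to 0.165 ± 0.0386 with DFO (log2 -2.56, SE 0.405, adjusted p = 0.00363) and 0.260 ± 0.0511 with T003 (-1.91, SE 0.385, adjusted p = 0.00801). The T003 call ended with limma-voom (adjusted p = 0.0574) and without T003 24 h replicate 2 (0.0731) or untreated replicate 2 (0.0621), where the log2 change was -1.15. IGHM, which is not in the B cell list, rose with both agents as given above, while MS4A1 and CD79B had 0 counts. The nuclear RNAs MALAT1 (79.5 CPM) and NEAT1 (373 CPM) had log2 changes of -0.02 and -0.03 with DFO and 0.08 and -0.04 with T003 at 24 h, none of which passed the test.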

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

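The tests on GC content and length, thinned libraries and single left-out libraries were set before their results were seen, and those on the shared untreated libraries and on time in culture only after. Between 6 h and 24 h, 4 genes and 2 gene lists moved differently with DFO than with T003, by the test of the interaction of agent and time itself. Among the genes, HMGCS1 had a log2 change of -0.09 with DFO and 0.37 with T003, a difference of -0.46 (SE 0.039, edgeR adjusted p = 0.00274). For LPIN1, a gene of lipid synthesis, they were 0.14 and 0.47 and the difference -0.33 (SE 0.042, adjusted p = 0.0392). HSPA5 changed by -0.35 and -0.66, a difference of 0.32 (SE 0.031, adjusted p = 0.00711). The LPIN1 call ended without each library but T003 6 h replicate 1 (adjusted p = 0.0533 to 0.228). The sterol synthesis list had medians of 0.016 with DFO and 0.158 with T003 and a median difference of -0.174 (camera adjusted p = 4.19e-15; adjusted p = 0.0607 with an estimated correlation). The endoplasmic reticulum list had medians of -0.105 and -0.147 and a median difference of 0.084 (adjusted p = 0.00249; adjusted p = 0.118 with an estimated correlation), and its call ended without T003 24 h replicate 2 (0.0569).

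Sterol genes were higher with T003 than with DFO at 24 h, with a median log2 difference of -0.178 for DFO minus T003. With the GC and length trends of each library removed the median was -0.184 (quartiles -0.265 and -0.123), which argues against such a trend as the whole cause. In libraries thinned to the smallest total it was -0.178 (quartiles -0.254 and -0.14). Thinning keeps the share of each gene in its library on average, so the median could hardly have moved. The thinned value therefore does not decide whether depth was a cause. Without each of the 4 libraries at 24 h the median stayed between -0.189 and -0.181, which argues against a single library as the whole cause. A candidate explanation left open is that the agents differ in their effect on sterol synthesis, as a hypothesis found and tested on the same libraries, since any difference in culture between the arms is not recorded in the labels.

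The 24 h changes of both agents ran together, and comparisons with the same untreated libraries share their chance values. The changes from 6 h to 24 h, which share no library between the agents, had a correlation of 0.661 across 10215 genes, which argues against the untreated libraries as the whole cause. With the GC and length trends removed it was 0.655. Time in culture cannot be told apart from the agents, because 0 untreated libraries at 24 h were analysed here. A response common to both agents and a change with time in culture may each account for part of it.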

How the results depend on the processing

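Counts are of genes called unless stated otherwise, and the cause of a change with a setting was not tested, except that fewer genes pass a demand on size. Leaving out a library leaves its group with 1 library, assumed to vary like the other groups. With a fold of at least 2, the counts were 3 and 67 for DFO and 3 and 119 for T003 at 6 h and 24 h, 7 between the agents at 24 h, 110 and 138 between times with DFO and T003, 0 for the interaction and 37 shared at 24 h. With no filter they were 16 for DFO at 6 h, 2 between the agents at 6 h and 16 for the interaction. The filter of 1 CPM gave 2 and 446 between the agents at 6 h and 24 h and 10 for the interaction. DESeq2 gave 522 for DFO and 81 for T003 at 6 h, 14 and 888 between the agents and 188 for the interaction, and limma-voom 25 for DFO at 6 h, 1 between the agents at 6 h and 19 for the interaction. A model of the compared groups alone gave 774 for DFO at 24 h, 2 and 49 between the agents and 1171 between times with DFO. Of the settings chosen after the data were seen, thinning gave 3 for DFO at 6 h, and removal of GC and length trends 2 between the agents at 6 h and 21 for the interaction, 10 higher and 11 lower against 1 and 3.

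Whether the replicate numbers pair the libraries was not settled. Deviations of libraries with the same number had a Pearson r of -0.344 to 0.325 over the 10 pairs of groups, over 0.1 in 2. These 2 were DFO at 24 h with DFO at 6 h (0.245) and with T003 at 6 h (0.325). The untreated group had -0.265 with DFO at 6 h, -0.344 with DFO at 24 h and -0.273 with T003 at 6 h. Spearman rho lay between -0.174 and 0.0716 over all pairs. With the replicate block the counts were 2 and 1185 for DFO and 1 and 2294 for T003 at 6 h and 24 h, 1 and 117 between the agents, 1809 and 2487 between times, 5 for the interaction and 895 shared. The crossed pairing, with the untreated numbers exchanged, gave 1 for T003 at 6 h and 132 between the agents at 24 h.

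Leaving out each library in turn gave 1 to 12 genes for DFO at 6 h, 437 to 1387 at 24 h, 1 to 13 for T003 at 6 h and 1164 to 2558 at 24 h. Between the agents it gave 0 to 3 at 6 h and 14 to 284 at 24 h, between times 980 to 1840 with DFO and 1369 to 2768 with T003, for the interaction 2 to 10 and for genes shared at 24 h 341 to 1033. Of 688 results for named genes 226 were called, and of 216 for lists 39. None of the called ones turned direction under any setting in which direction was compared, while 191 uncalled values of named genes changed sign. For lists, direction was not compared with an estimated correlation or with fry, so no turn could show there. Calls of lists gained with fry are therefore counted whatever their direction. RLE scaling changed no call of a named gene or list. Calls of named genes lost numbered 34 with the replicate block, 55 in the compared groups alone and 12 to 62 without single libraries. List calls lost numbered 34 with an estimated correlation, 4 with no filter, 3 with the block, 3 with fry, which gained 29, and 2 to 6 without single libraries. GC trends spanned 0.0146 to 0.207 log2 units per library, with the largest in DFO 6 h replicate 1 and the next, 0.115, in T003 24 h replicate 1. Why few genes were called at 6 h was not tested.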

Other observations

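Among the tests in this part, that on a TGF-beta response was set before its result was seen, on genes chosen after SKI, SKIL and LDLRAD4 were seen to fall, and both tests on HIF targets were chosen after the result was seen. The glycolysis list was not called at 24 h, and its members went both ways. HK2, the hexokinase that traps glucose in the cell, rose by 0.34 (log2, SE 0.037) with DFO and 0.33 (SE 0.037) with T003, and SLC16A1, a lactate transporter, rose by 0.26 (SE 0.024) and 0.27 (SE 0.024). HK1, another hexokinase, fell by 0.09 (SE 0.023) and 0.17 (SE 0.023), and GAPDH fell by 0.07 (SE 0.018) and 0.06 (SE 0.018). With T003, 7 of 34 genes of haem synthesis and iron-sulfur clusters fell while ALAS1 rose. FECH, which inserts iron into protoporphyrin to make haem, fell by 0.24 (SE 0.046, edgeR adjusted p = 0.00626). The FECH call ended without T003 24 h replicate 2. The TCA cycle genes OGDH and DLD fell by 0.17 (SE 0.026) and 0.15 (SE 0.026) with T003. RRM2, a subunit of the iron-dependent ribonucleotide reductase, rose by 0.13 (SE 0.020) and PCNA, the sliding clamp of DNA replication, fell by 0.13 (SE 0.023) with T003. PLOD2, an iron-dependent lysyl hydroxylase, fell by 0.58 (SE 0.093) with DFO and 0.60 (SE 0.093) with T003, and OASL, an interferon-stimulated gene, by 0.60 (SE 0.042) and 0.41 (SE 0.042).

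HIF targets did not rise as a list with DFO. The 23 members at 5 CPM or more had a median log2 change of -0.0709 at 24 h (quartiles -0.106 and 0.0456), which argues against low levels as the reason in these members. Members below 5 CPM were left out, and for them low levels remain open. Among those, levels in untreated cells and with DFO at 24 h were 0.302 and 0.315 CPM for VEGFA, 0.338 and 0.336 for BNIP3, and 4.45 and 4.06 for NDRG1. TFRC changed by 2.29 in the same libraries, but against cells at 0 h, so the agent cannot be told apart from time in culture. Whether the chelator acted on the cells, or entered the pool of iron used by the prolyl hydroxylases, cannot be told from TFRC. Oxygen and the stability of HIF proteins were not measured, and the reason may lie outside these data.

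SKI, SKIL and LDLRAD4, which dampen TGF-beta signalling and are induced by it, fell with both agents at 24 h, SKI by 0.96 (SE 0.064) and SKIL by 1.10 (SE 0.081) with DFO. These genes were singled out after their values were seen. A lower TGF-beta response could lower them and would then lower other targets. Of 20 genes listed as such targets, 17 were tested. With each agent 5 were higher (ID2, ID3, SMAD3, JUNB and NEDD9) and 1 lower (SMURF2). Whether TGF-beta raises or lowers each of them in NK-92 was not measured. If it lowers some, a lower response would raise those, so the list cannot decide on the response. The larger of both unadjusted camera p-values with an estimated correlation was 0.111, in the direction up, with medians of 0.016 and 0.0822. The condition worded beforehand against a lower response was a list that does not fall, with a median above 0, and both agents met that wording. The test as run was stricter and demanded lower quartiles above 0, which neither agent met. These quartiles were -0.08 with DFO and -0.0753 with T003, and the members went both ways, so the test did not decide. No fall of these targets as a list was seen, but a lower response in a part of them cannot be told apart from other causes.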
